A study of Mus musculus with 12 samples.

How the data were processed

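Expression was measured by RNA sequencing in gastrocnemius muscle of male mice of 2 genotypes (floxed WT and cFeimin MKO littermates) in 2 states (sedentary, and after running). Per the labels' protocols, total RNA was extracted with a GeneMark kit and measured on a NanoDrop, and libraries were made and sequenced by BGI on the DNBSEQ platform. The labels' protocols speak of 18 libraries; 12 were analysed here, 3 per group (replicates 1, 3 and 4 of sedentary WT, 1, 2 and 3 of sedentary MKO, 3, 4 and 5 of exercised WT, and 1, 2 and 4 of exercised MKO). One column name of the count table was misspelt and was taken as exercised MKO replicate 4, the only library left without a column.

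The values used were raw counts per Ensembl gene, as deposited, for 43432 gene identifiers. The submitters' processing notes name FastQC 0.12.1, HISAT2 2.2.1, SAMtools 1.9, StringTie 2.1.4, R 4.3 and DESeq2 1.40.2 and the builds GRCm38.p6 and mm10. Which tool made the counts, how strand and reads with several matches were treated, and the annotation release are not given in the sources used here. Symbols and positions were taken from GENCODE release M21 (GRCm38.p6), in which 42462 identifiers had a symbol; the 970 without held 0.0915% of the counts.

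Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14486, and libraries were scaled with TMM factors (0.928 to 1.15). All 12 libraries went into 1 quasi-likelihood model with 1 mean per group and 8 residual degrees of freedom. The comparisons were MKO with WT in each state, exercised with sedentary in each genotype, and the difference between the exercise responses. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and standard errors were derived from the F statistic. The biological coefficient of variation was 15.3%. Levels are normalised CPM as mean ± SD. The count totals were 14324010 to 14563501 and the 10 most abundant genes held 26.6% to 28.3% of them. P-values measure only the spread between these 12 samples, and the labels give no batch, litter or day.

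Gene lists (34: 22 of pathways and 12 of cell types) were fixed before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. The 32 lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Adjusted p-values run over the lists. Genes were named by rule: 7 genes in every comparison, among them Feimin, Sln, Foxc2 and Ucp3; the 8 largest changes each way among genes that passed, did not overlap between groups and reached 1 CPM; and up to 4 members of a list by p. The values of 1 gene that the rule names are not reported here. Floors for groups with no counts were 3 counts per library. List scores are means of log2 CPM (prior count 2), tested between genotypes by exact permutation within states (400 arrangements).

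Alternatives were DESeq2 1.42.0, limma-voom, 2 other scalings (median-of-ratios factors and total counts alone), no filter, a filter of 1 CPM in 3 libraries, only the compared groups, the replicate number as a block, and each library left out. Leaving out 3 outlying libraries together, averaging the genotype effect over the states, and most list medians with each library left out were added after the data were seen. Those of immediate-early genes between exercised MKO and WT, and of macrophage genes between MKO and WT, were fixed before. In simulated counts edgeR found 93.9% of 4-fold and 66.7% of 2-fold changes between genotypes at rest, with 4 false calls among 14263 genes. DESeq2 made 23 false calls in the same counts. Genes were simulated independently of each other, without shifts of whole libraries, so recovery in the real data may be lower. No replicates were duplicates of each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.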

Results

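Gene expression was measured by RNA sequencing in gastrocnemius, the main calf muscle, of male mice that were sedentary or had run for 90 min at 60% of their maximal running speed. The time between the run and sampling is not given in the sources used here. The mice were either WT (floxed at both alleles, with the gene intact) or cFeimin MKO (MKO below), in which cellular Feimin was knocked out. Each of the 4 groups (sedentary WT, sedentary MKO, exercised WT and exercised MKO) held 3 libraries, 12 in all, each labelled as a separate sample. The library protocol speaks of 18 libraries, of which 12 were analysed here. The count totals lay close together, between 14324010 and 14563501 per library, and 18502 to 19559 genes had at least 1 count. A total of 3 counts corresponded to 0.182 to 0.222 CPM (counts normalised to library size). Genes of the mitochondrial genome took 16.9% to 24.3% of the counts. The predicted genes Gm10925 and Gm28437 had nearly the same counts as mt-Atp6 and mt-Co3 in every library. In sedentary WT replicate 1 these were 259518 against 257472 and 296307 against 295937. The same reads may thus have been counted for both, which would affect this share and the count totals. The title and design of the study ask how cellular Feimin bears on running capacity and on heat production in muscle.

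Exercise was the main axis of the data. On the 1st principal component, which held 32.5% of the variance, the 6 exercised libraries lay between 12.4 and 39.6 and the 6 sedentary ones between -30.5 and -21.1. Exercised MKO replicates 1 and 4 (12.4 for both) lay nearer to the sedentary libraries than exercised MKO replicate 2 (28.4), which lay close to the exercised WT libraries (33.0, 35.4 and 39.6). Sedentary MKO replicate 3 also stood apart: it had the highest scaling factor (1.15) and the lowest mitochondrial share (16.9%), and its slow-fibre score, the mean log2 CPM of 14 slow-muscle genes, was 3.85 against 5.98 to 7.32 in the other 11 libraries.

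The targeted gene was examined first. Feimin was taken to be B230219D22Rik (ENSMUSG00000045767; chromosome 13, 55693124 to 55703500, plus strand, GRCm38, 2 exons), an assignment from general knowledge that the labels do not give. Its level was 22.6 ± 1.41 CPM (mean ± SD, n = 3) in sedentary WT and 4.92 ± 1.25 in sedentary MKO muscle, and 25.4 ± 4.15 in exercised WT and 4.06 ± 0.534 in exercised MKO muscle. In log2 fold change ± SE this was -2.21 ± 0.18 in sedentary muscle (edgeR, adjusted p = 0.000589) and -2.64 ± 0.18 in exercised muscle (adjusted p = 0.000114). Each of the 6 MKO libraries held fewer counts of it (49 to 92) than any WT library (293 to 405). This is the direction that the genotype labels give. Running itself gave no change of B230219D22Rik that passed, at 0.17 ± 0.16 in WT (adjusted p = 0.622) and -0.27 ± 0.20 in MKO (adjusted p = 0.594).

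**Figure D1:**
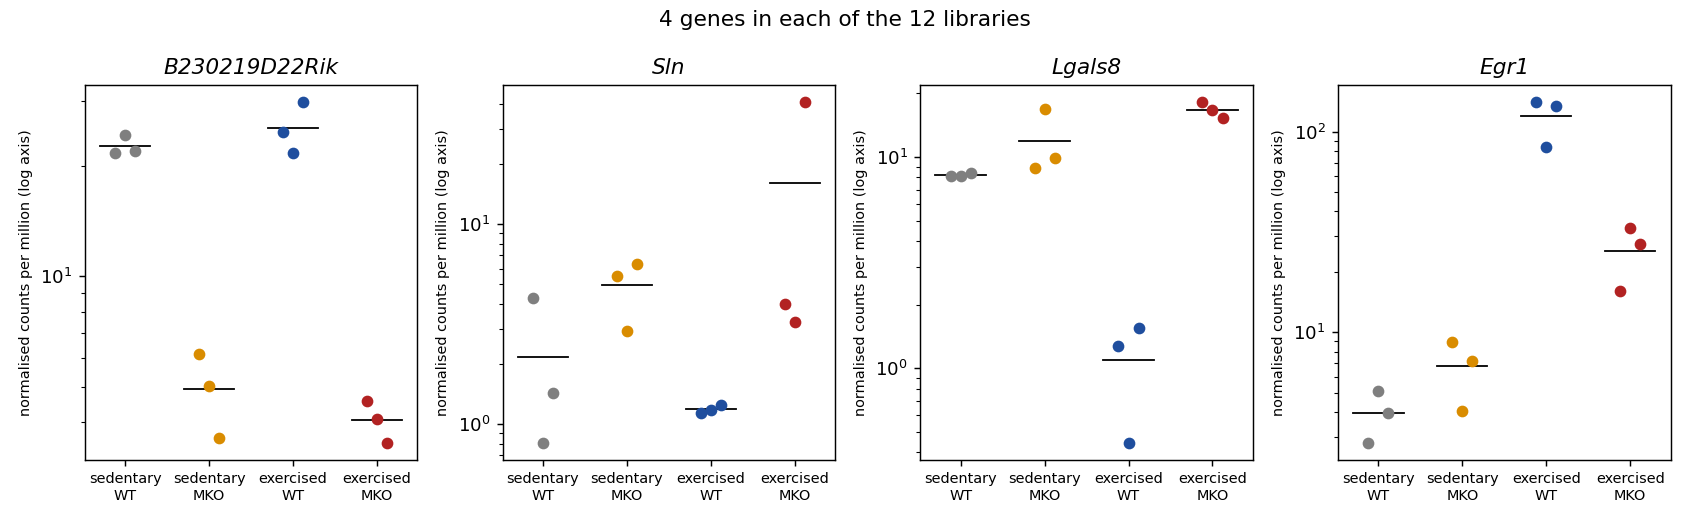
Normalised CPM (log axis) of B230219D22Rik, Sln, Lgals8 and Egr1 in the 12 libraries; points are single libraries and bars are group means (n = 3). B230219D22Rik averaged 4.92 and 4.06 CPM in the MKO groups against 22.6 and 25.4 in the WT groups, Sln spread from 3.26 to 40.8 CPM among exercised MKO libraries, and Lgals8 averaged 1.09 CPM in exercised WT against 16.7 in exercised MKO.

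The comparison of MKO with WT in sedentary muscle asks what loss of cellular Feimin does at rest. B230219D22Rik was the 1 gene of 14486 that passed; it fell. The genes picked in advance for muscle heat production did not pass. Sarcolipin (Sln; chromosome 9, 53850164 to 53854560, plus strand), the small peptide that uncouples the sarcoplasmic reticulum calcium pump, had a log2 fold change of 1.19 ± 0.95 (adjusted p = 1), which was 2.13 without sedentary WT replicate 1 and 0.80 without sedentary WT replicate 3. The pump genes Atp2a1 and Atp2a2 had -0.12 ± 0.14 and 0.35 ± 0.56, the mitochondrial carrier gene Ucp3 -0.32 ± 0.17 and the coactivator gene Ppargc1a -0.56 ± 0.43 (adjusted p = 1 for each). Foxc2 (chromosome 8, 121116171 to 121118895, plus strand), a transcription factor gene, had 2 to 7 counts per library and was not tested. Of the macrophage genes 13 of 13 had a positive log2 fold change (median 0.53), among them C1qc (0.58 ± 0.18) and Mrc1 (0.65 ± 0.24). So had 7 of 7 red blood cell genes (median 0.90), 21 of 23 extracellular matrix genes (median 0.31) and 10 of 10 Schwann cell genes (median 0.58). Single libraries moved these medians. The Schwann cell median turned to -0.27 without sedentary MKO replicate 1, and was 0.32 without sedentary WT replicate 3 and 0.92 without sedentary WT replicate 4. The red blood cell median was 0.54 without sedentary WT replicate 4 and 1.66 without sedentary WT replicate 3. The matrix median was 0.16 without sedentary WT replicate 4. Other cell types went another way. Of the smooth muscle and pericyte genes 8 of 10 were negative, and of 12 endothelial genes 7 were negative (median -0.012, or 0.06 with total counts alone as the library size). No member of the first 4 lists passed over all genes, and 0 passed adjusted over the list alone.

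By camera with a preset correlation of 0.01 between genes, 13 of 32 lists were called in sedentary muscle (9 higher and 4 lower in MKO), with adjusted p = 8.03e-10 for macrophage, 4.22e-07 for red blood cell, 6.44e-07 for matrix and 0.0449 for Schwann cell genes. None held: adjusted p = 0.328, 0.328, 0.476 and 0.821 with an estimated correlation for these 4, and the count of lists called was 0. The other 9 calls were also lost. Among them were atrophy and autophagy genes (median -0.11, adjusted p = 0.328 with an estimated correlation), inflammation genes (median 0.31, adjusted p = 0.328 with an estimated correlation) and satellite cell and myogenic genes (median 0.34, adjusted p = 0.328 with an estimated correlation). Fatty acid oxidation genes had 26 of 30 negative values (median -0.16), and the 13 mitochondrially encoded respiratory chain genes were all negative (median -0.21); adjusted p = 0.679 and 0.528 with an estimated correlation. For unfolded protein response, fibro-adipogenic progenitor, ribosomal protein, and smooth muscle and pericyte genes (medians 0.03, 0.21, 0.07 and -0.13), it was adjusted p = 0.476, 0.476, 0.855 and 0.635 with an estimated correlation. Several medians depended on 1 library. The fatty acid oxidation median was 0.05 without sedentary MKO replicate 3 (22 of 30 positive) and 0.02 without sedentary WT replicate 3, so its direction was not settled. The mitochondrially encoded median was -0.08 and -0.13 without the same 2 libraries. Without sedentary MKO replicate 3 the ribosomal protein, satellite cell and inflammation medians were 0.03, 0.12 and 0.15. The inflammation median was 0.16 without sedentary WT replicate 1 and 0.20 without sedentary WT replicate 4. The fibro-adipogenic median was 0.09 without sedentary WT replicate 4, 0.11 without sedentary MKO replicate 1 and 0.33 without sedentary WT replicate 3. The satellite cell median was 0.23 without sedentary WT replicate 4. Without sedentary WT replicate 3 the smooth muscle and atrophy medians were -0.03 and -0.24, and without sedentary WT replicate 1 they were -0.27 and -0.06. Fewer genes had an unadjusted p under 0.05 (545) than the 724 that chance alone would give.

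The comparison of MKO with WT in exercised muscle asks what the loss does after the run. Besides B230219D22Rik, 4 genes passed. Galectin-8 (Lgals8; chromosome 13, 12439415 to 12464944, minus strand), a sugar-binding lectin that marks damaged endosomes and lysosomes, rose by 3.93 ± 0.33 (adjusted p = 0.000452): it stood at 1.09 ± 0.576 CPM in exercised WT and 16.7 ± 1.46 in exercised MKO muscle. Egr1 (chromosome 18, 34859823 to 34864984, plus strand), an immediate-early transcription factor, was lower in MKO by 2.22 on the log2 scale (log2 fold change -2.22 ± 0.31, adjusted p = 0.0424), at 25.5 ± 8.64 CPM against 119.1 ± 31.1. The axon guidance gene Sema3a (chromosome 5, 13125414 to 13602565, plus strand) fell to 0.403 from 1.60 CPM (-1.96 ± 0.27, adjusted p = 0.0411). Mnt (chromosome 11, 74830920 to 74845725, plus strand), which encodes a partner of MAX that opposes MYC, fell to 25.7 from 41.9 CPM (-0.70 ± 0.096, adjusted p = 0.0411). Lgals8 overlaps Heatr1 on the opposite strand by 155 exonic bases, and whether counting used strand is not given in the sources used here; Heatr1 itself stood at 6.17 CPM in exercised MKO against 7.45 in exercised WT.

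Sln was higher in the 3 exercised MKO libraries (3.26 to 40.8 CPM) than in the 3 exercised WT libraries (1.13 to 1.25 CPM), but did not pass: the log2 fold change was 3.74 ± 0.99 (adjusted p = 0.203) and 1.59 without exercised MKO replicate 4, the library with 40.8 CPM. With both states in one test, added after the data were seen, Sln averaged 2.01 log2 units higher in MKO (exact permutation test within states, two-sided, p = 0.01). The smallest p that the 400 arrangements can give is 0.005, and the value was not adjusted over genes. All 14 slow-fibre genes had positive values beside it in the exercised muscle (median 0.37, 0 passing over all genes and 0 adjusted over the list alone; not called, adjusted p = 0.138). Ucp3 (0.12 ± 0.17, adjusted p = 0.748), Ppargc1a (-0.35 ± 0.42, adjusted p = 0.696), Atp2a1 (-0.21 ± 0.14, adjusted p = 0.466) and Atp2a2 (0.13 ± 0.56, adjusted p = 0.925) did not pass. The value of Ppargc1a was 0.38 without exercised WT replicate 5. The thermogenesis list had 10 of 21 positive values (median -0.06) and no member past the threshold, over all genes or adjusted over the list alone.

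Immediate-early genes had mostly negative values. Of 31 members 25 had a negative value (median -0.50); Egr1 passed over all genes, and Egr1 and Fosb (-2.11 ± 0.39) passed adjusted over the list alone. Circadian clock genes had 16 of 18 negative values (median -0.39); none passed over all genes and Cry2, a repressor of the clock, passed adjusted over the list alone (-0.93 ± 0.20). Macrophage genes were all 13 positive (median 0.89): none passed over all genes, while 8 passed adjusted over the list alone, among them the complement genes C1qa (1.03 ± 0.26) and C1qc (0.89 ± 0.19), the mannose receptor gene Mrc1 (1.14 ± 0.26) and Cd68 (1.93 ± 0.58). Extracellular matrix genes were positive for 22 of 23 (median 0.41, 0 adjusted over the list alone), ribosomal protein genes for 32 of 33 (median 0.23, 2 adjusted over the list alone) and nuclear genes of the respiratory chain for 45 of 47 (median 0.19, 0 adjusted over the list alone), and none of these passed over all genes. Exercised MKO replicate 2 lay near the WT libraries. Its matrix score (mean log2 CPM) was 3.48 against 3.50 to 3.62 in exercised WT, and 4.24 and 4.50 in exercised MKO replicates 1 and 4. Its macrophage score was 2.11 against at most 2.05 in exercised WT. The matrix median was 0.27 without exercised MKO replicate 4. The ribosomal median 0.15 without exercised WT replicate 5, and the respiratory chain median 0.11 without exercised WT replicate 5 and 0.12 without exercised MKO replicate 4.

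Camera with the preset correlation called 8 lists in exercised muscle, with adjusted p = 1.1e-05 for immediate-early, 1.88e-05 for clock, 2.85e-09 for macrophage, 3.09e-06 for matrix, 5.3e-10 for ribosomal and 8.59e-06 for respiratory chain genes. With an estimated correlation all 8 calls were lost: adjusted p = 0.622, 0.193, 0.323, 0.622, 0.622 and 0.867 for these 6, in that order. By fry 1 of the 8 was kept, a list lower in MKO. For the other 2, fibro-adipogenic progenitor genes (10 of 12 positive, median 0.41) and atrophy and autophagy genes (15 of 22 negative, median -0.14), it was adjusted p = 0.587 and 0.622 with an estimated correlation. The gene count depended on exercised MKO replicate 2, without which 108 genes passed instead of 5, and without exercised WT replicate 5 or exercised MKO replicate 1 it was 2; DESeq2 called 95 genes, the 5 included. Lgals8 and B230219D22Rik passed without any single library, whereas Egr1, Sema3a and Mnt each missed the threshold without exercised WT replicate 3 (adjusted p = 0.113 for each), exercised WT replicate 5 (0.205 for each), exercised MKO replicate 1 (0.217, 0.192 and 0.26) or exercised MKO replicate 4 (0.239 for each). Sema3a and Mnt also missed it without exercised WT replicate 4 (0.05 and 0.107). At an unadjusted p under 0.05 there were 2319 genes, against 724 by chance. There were 1020 without exercised MKO replicate 4, 1429 without exercised WT replicate 5 and 984 without the 3 outlying libraries (sedentary MKO replicate 3, exercised WT replicate 5 and exercised MKO replicate 4). Other splits of these 6 libraries gave up to 1098.

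**Figure D2:**
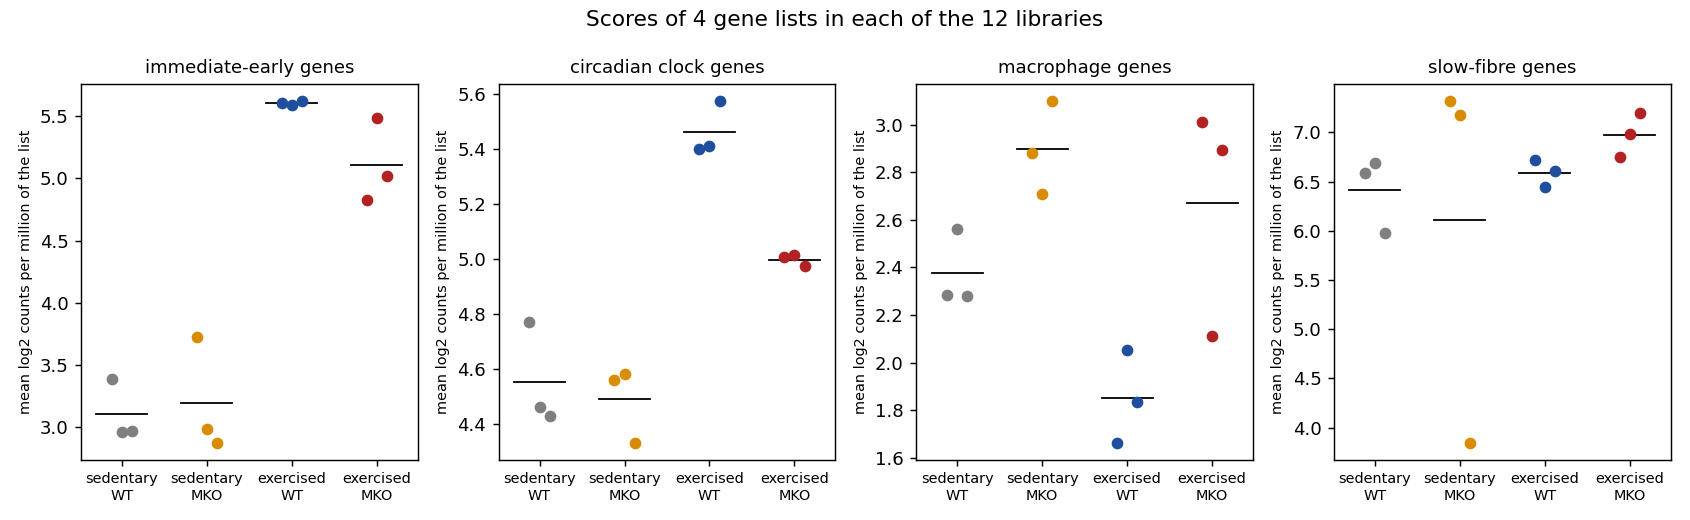
Mean log2 CPM of the immediate-early, circadian clock, macrophage and slow-fibre lists in the 12 libraries; points are single libraries and bars are group means (n = 3). Exercised WT libraries had clock scores of 5.40 to 5.58 against 4.98 to 5.01 in exercised MKO, and sedentary MKO replicate 3 had a slow-fibre score of 3.85.

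The comparison of exercised with sedentary WT muscle shows how muscle after the run differed from muscle at rest. The labels give no hour of sampling, so a difference in hour cannot be told apart from the run. A broad set of transcription factors of the immediate response rose. The orphan nuclear receptor gene Nr4a2 rose by 7.21 ± 0.36 on the log2 scale (adjusted p = 1.09e-06), and the AP-1 genes Fosb, Junb and Fosl2 by 7.49 ± 0.61, 6.66 ± 0.44 and 4.50 ± 0.26; Egr1 rose by 4.90 ± 0.37, from 3.97 ± 1.15 to 119.1 ± 31.1 CPM. Of 31 immediate-early genes 20 rose and 1 fell over all genes, and 22 rose and 3 fell adjusted over the list alone (median 1.91); the call held, adjusted p = 0.0202 with an estimated correlation. In all, 1193 of 14486 genes passed, 599 higher and 594 lower, of which 589 had a change of more than 2-fold.

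Clock genes followed. Ciart, a repressor of the clock, rose by 5.37 ± 0.37 (adjusted p = 1.07e-05), from 1.05 to 43.6 CPM, and Cry2, Per1 and Bhlhe40 rose by 1.98 ± 0.20, 1.94 ± 0.31 and 1.32 ± 0.13. Of 18 clock genes 6 rose over all genes and 9 adjusted over the list alone, and none fell (median 0.55, or 0.37 without sedentary WT replicate 4; adjusted p = 0.0202 with an estimated correlation). The labels do not give the hour at which either group was sampled. Heat shock genes rose as well: the inducible chaperone genes Hspa1a and Hspa1b by 2.67 ± 0.26 and 2.91 ± 0.29, Hsp90aa1 by 1.75 ± 0.19 and Dnaja1 by 1.24 ± 0.13. Of 27 heat shock genes 7 rose over all genes, and 13 rose and 1 fell adjusted over the list alone (median 0.37), though this call was lost, adjusted p = 0.171 with an estimated correlation. Oxidative stress genes rose in part, with Srxn1 at 2.31 ± 0.24, the transcription factor gene Nfe2l2 at 1.31 ± 0.23 and the metallothionein genes Mt1 and Mt2 at 2.83 ± 0.61 and 3.53 ± 0.77; these were the 4 of 19 that rose over all genes, 5 rose adjusted over the list alone, and the call was lost, adjusted p = 0.295 with an estimated correlation.

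Genes of metabolism went both ways. The kinase gene Sik1 (4.28 ± 0.34), the cAMP-responsive repressor gene Crem (2.22 ± 0.22) and hexokinase 2 (Hk2, 1.18 ± 0.13), which traps glucose in the cell, rose. Pdk4, the kinase that shuts off pyruvate dehydrogenase, fell by 2.71 (-2.71 ± 0.27, adjusted p = 0.000105), from 1409 ± 238 to 215.5 ± 75.0 CPM, and Angptl4, an inhibitor of lipoprotein lipase, fell by 3.29 (-3.29 ± 0.55). Cited2, a regulator of hypoxia signalling (-3.03 ± 0.18), the hormone-sensitive lipase gene Lipe (-0.93 ± 0.13), the thioesterase gene Acot1 (-1.75 ± 0.31) and the atrophy ligase gene Fbxo32 (-0.98 ± 0.17) fell too, while Foxo1 rose by 1.76 ± 0.41. Of 32 exercise-response genes 7 rose and 4 fell, over all genes and adjusted over the list alone alike, with a call that was lost, adjusted p = 0.515 with an estimated correlation. Of 30 fatty acid oxidation genes 29 had a negative value (median -0.24), 4 fell over all genes and 4 adjusted over the list alone; adjusted p = 0.708 with an estimated correlation, and the median was -0.07 without sedentary WT replicate 3. Fbxo32 overlaps Gm15943, which also fell (by 2.17), on the opposite strand by 186 exonic bases, and Cry2 overlaps D930015M05Rik on the opposite strand by 295. D930015M05Rik also rose, from 0 counts in sedentary WT to 1.31 CPM (adjusted p = 0.00318).

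The thermogenesis genes moved both ways in WT muscle. Ucp3 fell by 0.85 (-0.85 ± 0.17, adjusted p = 0.00816), from 363.2 ± 69.9 to 201.5 ± 14.8 CPM, while the deiodinase gene Dio2, which activates thyroid hormone, rose by 1.69 ± 0.31 (1.20 to 3.92 CPM), Cidea, a lipid droplet gene typical of brown fat, by 2.21 ± 0.46 (1.09 to 5.07 CPM), and Ppard by 0.46 ± 0.10. Of 21 members 5 rose and 1 fell over all genes and adjusted over the list alone (median 0.20, or 0.09 without sedentary WT replicate 3); the call was lost, adjusted p = 0.493 with an estimated correlation. Ppargc1a had 1.14 ± 0.43 (adjusted p = 0.136), Sln -0.86 ± 1.16 (adjusted p = 0.747), Atp2a1 0.20 ± 0.14 (adjusted p = 0.459) and Atp2a2 0.21 ± 0.56 (adjusted p = 0.884). The calcium-handling gene Trdn (triadin) rose by 1.29 ± 0.26, the 1 of 25 of its list to pass over all genes and adjusted over the list alone.

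Connective tissue genes were lower after the run. Of 12 fibro-adipogenic progenitor genes 8 fell over all genes and 12 adjusted over the list alone (median -0.91), with Pdgfra at -1.63 ± 0.14 (adjusted p = 4.17e-05), Cd34 at -0.73 ± 0.09 and Smoc2 at -0.96 ± 0.13. The call held, adjusted p = 0.0202 with an estimated correlation. Of 23 matrix genes 10 fell over all genes, and 19 fell and 1 rose adjusted over the list alone (median -0.86), with Col6a1 at -1.12 ± 0.15 and Mmp2 at -0.87 ± 0.15, but adjusted p = 0.295 with an estimated correlation. The pericyte gene Pdgfrb (-1.22 ± 0.13), the apelin receptor gene Aplnr (-2.28 ± 0.21) and the endothelial receptor gene Tek (-0.97 ± 0.18) fell, whereas the tight junction gene Cldn5 rose by 1.61 ± 0.21, Flt1 by 0.75 ± 0.18, Esam by 0.52 ± 0.14 and Thbs1 by 2.46 ± 0.33. Of 10 smooth muscle and pericyte genes 3 fell over all genes and adjusted over the list alone, adjusted p = 0.493 with an estimated correlation. Of 13 macrophage genes 2 fell over all genes, Cd163 (-0.94 ± 0.19) and C1qc (-0.72 ± 0.19), and 7 fell and 1 rose adjusted over the list alone (median -0.63, or -0.42 without sedentary WT replicate 3; adjusted p = 0.529 with an estimated correlation). Tril, a co-receptor for bacterial lipopolysaccharide, fell by 2.83, and Lgals8 fell by 2.91 (-2.91 ± 0.34, adjusted p = 0.000291), from 8.24 ± 0.177 to 1.09 ± 0.576 CPM.

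Some of the largest changes in WT rested on groups with no counts at all, so that only bounds can be given. Against a floor of 3 counts per library, C2cd4b was at least 12.8-fold higher after exercise, the acetylcholine receptor subunit gene Chrna9 at least 7.26-fold, the arginase gene Arg1 at least 6.08-fold, Gnat1 at least 5.23-fold and Bex4 at least 5.20-fold higher, and Cpt1c at least 4.69-fold lower. These genes reached only 1.03 to 2.62 CPM in their higher group.

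Camera with the preset correlation called 14 of 32 lists in WT (8 higher, 6 lower), of which 3 held with an estimated correlation: immediate-early, clock and fibro-adipogenic progenitor genes. By fry 7 of the 14 were kept. The remaining calls not yet given were glucocorticoid targets (6 of 20 rose; adjusted p = 0.493 with an estimated correlation), lipid synthesis genes (median 0.23; adjusted p = 0.0734 with an estimated correlation) and ribosomal protein genes (0 of 33 passing, median -0.19, or -0.08 without exercised WT replicate 5; adjusted p = 0.708 with an estimated correlation). Without sedentary MKO replicate 3, exercised WT replicate 5 and exercised MKO replicate 4, a choice made after the data were seen, none of the 3 held: adjusted p = 0.136, 0.0618 and 0.136 with an estimated correlation. The balance of directions depended on scaling: with total counts alone as the library size, 469 genes were higher and 863 lower, and the median of all genes moved from -0.01 to -0.10. Values are therefore relative to the middle of all genes, which TMM scaling sets near 0.

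The same comparison in MKO muscle shows the response with B230219D22Rik reduced, though still at 4.92 CPM in sedentary and 4.06 CPM in exercised muscle. The same kinds of genes led it: Nr4a2 rose by 6.10 ± 0.34 (adjusted p = 6.16e-06), Junb by 5.17 ± 0.41, Fosb by 4.91 ± 0.61, Nr4a3 by 4.47 ± 0.43 and Fosl2 by 4.02 ± 0.26. Egr1 had 1.91 here, and 17 of 31 immediate-early genes rose over all genes and 20 adjusted over the list alone, with none falling (median 1.18, adjusted p = 0.0298 with an estimated correlation). Ciart rose by 4.33 ± 0.36, Per1 by 1.55 ± 0.31, Cry2 by 1.23 ± 0.20 and Bhlhe40 by 0.81 ± 0.13. Of 18 clock genes 6 rose over all genes and adjusted over the list alone; the call held, adjusted p = 0.044 with an estimated correlation, while the list median of 0.10 became -0.05 with total counts alone as the library size, 0.06 without exercised MKO replicate 1 and 0.21 without exercised MKO replicate 4. In all, 586 genes passed in MKO, 332 higher and 254 lower.

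Chaperone, stress and metabolic genes changed in MKO muscle too. Hspa1a rose by 2.13 ± 0.26, Hspa1b by 2.45 ± 0.28, Hsp90aa1 by 1.39 ± 0.18 and Srxn1 by 1.57 ± 0.24. Of 27 heat shock genes 7 rose over all genes and 12 adjusted over the list alone (median 0.27, adjusted p = 0.103 with an estimated correlation), and of 19 oxidative stress genes 2 rose over all genes and 3 adjusted over the list alone (median 0.15, or -0.01 with total counts alone; adjusted p = 0.103 with an estimated correlation). Sik1 rose by 3.58 ± 0.33, Crem by 1.75 ± 0.21 and Hk2 by 0.85 ± 0.13, and Pdk4 fell by 1.69 (-1.69 ± 0.26, adjusted p = 0.00369), from 1083 ± 189 to 335.5 ± 87.3 CPM. Cited2 (-2.33 ± 0.17), Lipe (-0.52 ± 0.12) and Fbxo32 (-0.74 ± 0.17) fell. Of 32 exercise-response genes 7 rose and 1 fell over all genes, and 8 rose and 3 fell adjusted over the list alone (median 0.12, or -0.01 with total counts alone; adjusted p = 0.266 with an estimated correlation). Among thermogenesis genes Cidea rose by 2.50 ± 0.49, Dio2 by 1.37 ± 0.32, Ppard by 0.54 ± 0.10 and Slc25a5 by 0.47 ± 0.12: 4 of 21 rose over all genes and 5 adjusted over the list alone (median 0.21, adjusted p = 0.242 with an estimated correlation). Ucp3 (-0.41 ± 0.17, adjusted p = 0.262), Ppargc1a (1.34 ± 0.43, adjusted p = 0.124), Atp2a1 (0.12 ± 0.14, adjusted p = 0.783), Atp2a2 (-0.01 ± 0.56, adjusted p = 0.999) and Sln (1.69 ± 0.82, adjusted p = 0.367; -0.45 without exercised MKO replicate 4) did not pass.

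Connective tissue genes were again lower. Of 12 fibro-adipogenic progenitor genes 6 fell over all genes and 7 adjusted over the list alone (median -0.71), with Pdgfra at -1.22 ± 0.13 (adjusted p = 0.000499), and the call held, adjusted p = 0.0298 with an estimated correlation. Of 23 matrix genes 5 fell over all genes, and 14 fell and 1 rose adjusted over the list alone (median -0.67, adjusted p = 0.251 with an estimated correlation). Col6a1 (-0.84 ± 0.15), Mmp2 (-0.78 ± 0.15), Tril (-2.49 ± 0.27), Aplnr (-2.27 ± 0.20), the antiviral gene Rsad2 (-2.36 ± 0.29), Cd163 (-0.90 ± 0.18) and Pdgfrb (-1.10 ± 0.13) fell. Pcdhgb8, which also passed, shares 2116 exonic bases with its neighbours in the protocadherin gamma cluster, so its value is uncertain. Vdr and C2cd4b rose from groups with 2 and 3 counts in total, to 1.27 ± 0.324 and 2.03 ± 1.22 CPM. Red blood cell genes had negative values in 6 of 7 cases (median -1.38), with none past the threshold over all genes and 5 adjusted over the list alone, among them Hbb-bs (-1.53 ± 0.39).

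Camera with the preset correlation called 14 lists in MKO (9 higher, 5 lower), and the same 3 as in WT held with an estimated correlation. By fry 7 of the 14 were kept. Without the same 3 libraries the 3 lists did not hold either, at adjusted p = 0.201, 0.129 and 0.129 with an estimated correlation. The other lost calls were nuclear and mitochondrial respiratory chain genes (46 of 47 and 13 of 13 positive, medians 0.18 and 0.26, or 0.03 and 0.15 without sedentary MKO replicate 3, with the nuclear one 0.11 without exercised MKO replicate 4; adjusted p = 0.759 and 0.743 with an estimated correlation). Also lost were glucocorticoid targets (median 0.25; adjusted p = 0.743 with an estimated correlation), red blood cell genes (adjusted p = 0.294 with an estimated correlation), adipocyte genes (median -0.52; adjusted p = 0.46 with an estimated correlation) and smooth muscle and pericyte genes (median -0.25; adjusted p = 0.46 with an estimated correlation). The gene count was 316 without exercised MKO replicate 2 and 341 without sedentary MKO replicate 2. With total counts alone as the library size, 259 genes were higher and 596 lower, and the median of all genes moved from 0.00 to -0.15.

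**Figure D3:**
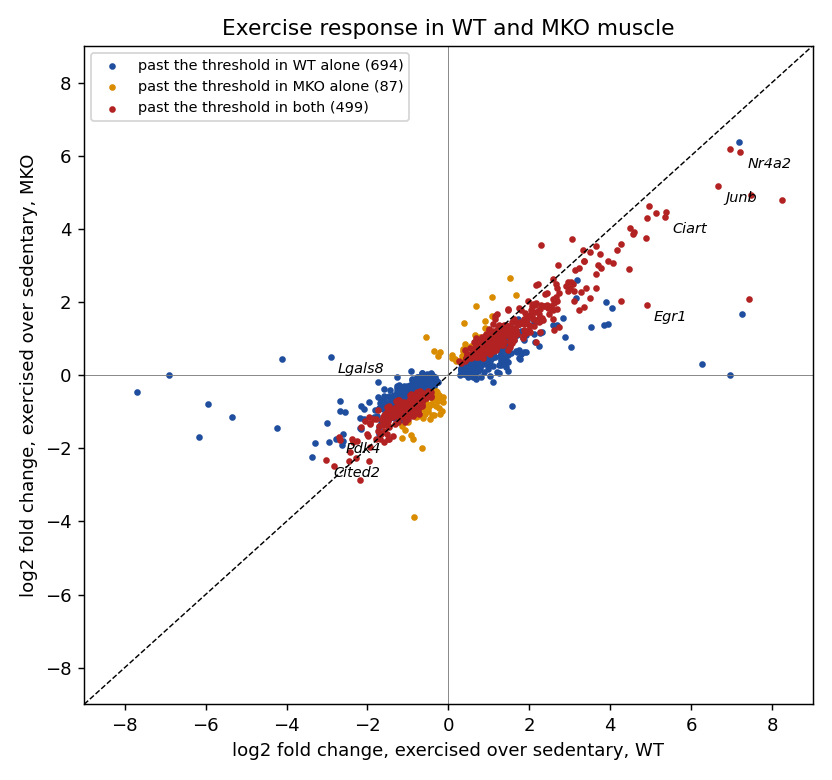
Log2 fold change of exercised over sedentary muscle in MKO (vertical) against WT (horizontal), 1 point per gene past the threshold in WT alone (694), in MKO alone (87) or in both (499); the dashed line marks equal values, and the fitted values of genes with no counts in a group are not bounds. Nr4a2, Junb and Ciart lie at the upper right (7.21, 6.66 and 5.37 in WT), Pdk4 and Cited2 at the lower left (-2.71 and -3.03 in WT), and Lgals8 off the line (-2.91 in WT).

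The overlap of the exercise responses was tested next. The 2 comparisons share no library. They called 499 genes in common, 298 higher and 201 lower in both, and 0 in opposite directions, against 13.7 and 10.4 for independent lists of these sizes. Of the 1193 genes called in WT, 1176 (98.6%) had the same sign in MKO. Across all 14486 genes the log2 fold changes correlated with Pearson's r = 0.60 and Spearman's rho = 0.534; genes are not independent replicates, so no p is given. Among the shared genes the WT change was the larger in 374 of 499, and the median ratio of MKO to WT was 0.855. Without exercised MKO replicate 2 the shared count was 286.

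The difference between the 2 responses was tested directly as an interaction. Lgals8, which fell in WT and stood at 11.9 ± 4.37 CPM in sedentary and 16.7 ± 1.46 in exercised MKO muscle, had the smallest p: its response was 3.40 ± 0.42 log2 units higher in MKO (adjusted p = 0.0591), which did not pass in edgeR. It passed in DESeq2 (adjusted p = 7.68e-11) and limma-voom (0.0331), with total counts alone (0.0471) and without sedentary MKO replicate 2 (0.00609). With median-of-ratios factors, no filter, the stricter filter or the replicate block, edgeR called 0 genes, so Lgals8 did not pass there. The same held without sedentary WT replicate 3 or 4, sedentary MKO replicate 1 or 3, any exercised WT library, or exercised MKO replicate 1 or 4. Egr1 (-2.99 ± 0.48, adjusted p = 0.254) had a smaller rise in MKO and did not pass, though it did in DESeq2 (adjusted p = 5.73e-07). Sln (2.55 ± 1.41, adjusted p = 0.983; 0.40 without exercised MKO replicate 4), Ucp3 (0.44 ± 0.24, adjusted p = 0.983), Ppargc1a (0.20 ± 0.60, adjusted p = 0.989), Atp2a1 (-0.09 ± 0.19, adjusted p = 0.983), Atp2a2 (-0.22 ± 0.79, adjusted p = 0.992) and B230219D22Rik (-0.44 ± 0.25, adjusted p = 0.983) did not pass either. edgeR called 0 genes, with 534 at an unadjusted p under 0.05 against 724 by chance, while DESeq2 called 3 and limma-voom 4. For this comparison in simulated counts DESeq2 made 18 false calls against 4 by edgeR, so its additional calls need caution. In simulated counts with the same design, edgeR recovered 80.0% of the 4-fold, 30.6% of the 2-fold and 3.03% of the 1.5-fold differences of this kind. Smaller differences between the responses would therefore mostly have been missed. Genes were simulated independently of each other, without the shifts of whole libraries seen here, so larger differences may have been missed as well.

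Across lists, immediate-early genes had a smaller response in MKO for 26 of 31 members (median difference -0.64, or -0.14 without sedentary MKO replicate 1), with 1 passing adjusted over the list alone and none over all genes; adjusted p = 0.898 with an estimated correlation. Clock genes had a smaller response for 13 of 18 (median -0.39, or -0.20 without exercised WT replicate 5; adjusted p = 0.268 with an estimated correlation). So had lipid synthesis genes for 21 of 27 (median -0.19, or -0.09 without sedentary MKO replicate 1 and -0.10 without exercised MKO replicate 4; adjusted p = 0.188 with an estimated correlation). Nuclear respiratory chain genes had a higher value for 47 of 47 (median 0.21, but 0.05 with 31 of 47 positive without sedentary MKO replicate 3, and 0.12 without exercised WT replicate 5; adjusted p = 0.922 with an estimated correlation). So had fatty acid oxidation genes for 29 of 30 (median 0.29, but 0.10 with 22 of 30 positive without sedentary MKO replicate 3, and 0.13 without sedentary WT replicate 3; adjusted p = 0.922 with an estimated correlation). The other lost calls were ribosomal protein genes (33 of 33 positive, median 0.17, or 0.08 without exercised WT replicate 5), glucocorticoid targets (15 of 20 negative, median -0.21, or -0.10 without sedentary WT replicate 3) and red blood cell genes (6 of 7 negative, median -0.47, or -0.12 without sedentary WT replicate 4), each at adjusted p = 0.922 with an estimated correlation. The preset correlation called 8 lists in this comparison and an estimated correlation 0, as did fry.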

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

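The tests of a single exercised MKO library and of slow muscle as the whole cause of the Sln difference, and those of blood and of muscle fibre share for the macrophage genes, were chosen after the result was seen. So were the comparison averaged over states and most list medians with single libraries left out. Those of immediate-early genes between exercised MKO and WT, and of macrophage genes between MKO and WT, were fixed before.

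Of the gene lists, 8 had exercise responses that differed between MKO and WT by camera with the preset correlation. The median difference, MKO minus WT, was -0.64 for immediate-early genes, -0.21 for glucocorticoid targets, 0.21 for nuclear respiratory chain genes, 0.29 for fatty acid oxidation genes, -0.19 for lipid synthesis genes, -0.39 for clock genes, 0.17 for ribosomal protein genes and -0.47 for red blood cell genes. With an estimated correlation 0 of the 8 held. Of 100 splits of the samples, the real one included, 85 called at least as many lists as the real 8. The highest other was 20, so chance cannot be excluded for these calls. At the level of genes, 50 of 100 splits had as many genes at an unadjusted p under 0.05 as the real 534. The highest other, 2245, was the genotype grouping with its labels swapped in 1 state, so a genotype effect common to both states also raises the counts of other splits. Without it the highest other was 2124, and 49 of 99 splits had as many. The split with 2124 kept the exercised libraries grouped by genotype and mixed only the sedentary ones, so it can carry a genotype effect too. The share of splits is therefore not free of genotype effects. A split that mixed genotypes in both states had 1339 such genes against the real 534. Single libraries carried much of some medians: without sedentary MKO replicate 1 the immediate-early difference was -0.14, and without sedentary MKO replicate 3 the respiratory chain difference was 0.05 and the fatty acid oxidation difference 0.10.

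Immediate-early genes had a median log2 fold change of -0.50 in exercised MKO against exercised WT. A single library is argued against as the cause, since the value nearest to 0 with any of the 6 libraries left out was -0.34 (without exercised MKO replicate 4). The shift rested on 2 of the 3 exercised MKO libraries, however: the mean log2 CPM of the list was 4.83 and 5.02 in replicates 1 and 4, and 5.49 in replicate 2, close to the 5.59 to 5.62 of exercised WT. GC content and transcript length are argued against as well: of 1000 lists matched for both, 0 percent had a median as low, and their middle 95% ran from -0.056 to 0.115. A weaker or faster-fading transcription response in MKO may explain it, but so may a different time between run and sampling, which no label gives. Egr1, the gene of this list that passed, had adjusted p from 4.82e-09 (DESeq2) to 0.376 (without the 3 outlying libraries) over the alternatives, and no longer passed without exercised WT replicate 3 (0.113) or 5 (0.205), or without exercised MKO replicate 1 (0.217) or 4 (0.239).

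Sln was higher in exercised MKO than exercised WT by 3.74 on the log2 scale without passing the test. Without exercised MKO replicate 4 the value was 1.59, so that library alone does not account for the sign, though it accounts for much of the size. Slow muscle in the tissue piece stays open as a part of the cause: 3 of 3 exercised MKO libraries had a slow-fibre score above every exercised WT library. At rest, however, sedentary MKO replicate 3 had the lowest score (3.85) and the highest Sln (2.70 log2 CPM) of the 6 sedentary libraries. Slow muscle cannot be told apart as the whole cause either. The scores differed by 0.388 and Sln by 2.65, which leaves 2.26 (1.22 without exercised MKO replicate 4) if Sln follows the score one for one. The slope is not settled by these data: within the exercised groups Sln moved by 5.44 per unit of the score, at which 0.54 is left, and by -0.60 without exercised MKO replicate 4. Higher Sln transcription in MKO fibres may also contribute, as a hypothesis found and examined on the same data.

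Macrophage genes had higher values in MKO in both states (medians 0.53 and 0.89). Blood in the tissue piece is argued against in exercised muscle, where the red blood cell median was 0.35 against 0.89 for macrophages, but in sedentary muscle it was 0.90 (0.54 without sedentary WT replicate 4) and blood stays open there. No single library carried the pattern, as the lowest ratio of the median without 1 library to its full value was 0.803. In exercised muscle, however, it rested mainly on MKO replicates 1 and 4 (macrophage scores 3.01 and 2.89). The score of exercised MKO replicate 2 was 2.11, close to the 1.66 to 2.05 of exercised WT. A lower share of muscle fibres that raises the markers of all other cell types alike is argued against. The highest median of the endothelial and smooth muscle lists in either state was -0.012 (endothelial, sedentary, or 0.06 with total counts alone as the library size). The upper quartiles of both lists (at most 0.046) lay below the lower quartiles of the macrophage list (0.45 and 0.53). These lists cannot decide on a lower fibre share that raises other cell types unevenly, which stays open. A shift in several cell types at once stays open, because fibro-adipogenic (0.21 and 0.41), Schwann cell (0.58 and 0.31) and satellite cell (0.34 and 0.12) medians were also above 0 in the 2 states; the Schwann cell medians turned to -0.27 without sedentary MKO replicate 1 and -0.10 without exercised MKO replicate 1. More macrophages, or a higher expression of these genes per cell, may lie behind it, and these 2 were not separated.

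For the comparisons of 3 with 3 libraries there are only 10 splits, too few for a share under 0.05. Between genotypes at rest, 2 of 10 splits called as many genes (real 1, highest other 1) and 7 of 10 as many lists (real 13, highest other 17); in exercised muscle 1 of 10 as many genes (real 5, highest other 1) and 5 of 10 as many lists (real 8, highest other 15). For exercise in WT it was 1 of 10 for genes (real 1193, highest other 1) and 3 of 10 for lists (real 14, highest other 17), and in MKO 1 of 10 for genes (real 586, highest other 1) and 7 of 10 for lists (real 14, highest other 21). For the genes shared between the exercise responses, 1 of 100 pairs of splits, the real one, gave 499, with 0 as the highest other, so chance can be excluded for the exercise grouping. The splits do not measure how large an overlap chance gives between 2 real responses, since any other split of a genotype called at most 1 gene. For the genotype effect averaged over states, 8 of 100 splits called as many genes (real 2, highest other 3) and 59 of 100 as many lists (real 11, highest other 20), so chance cannot be excluded for either. By the count at an unadjusted p under 0.05, a measure chosen after the result was seen, 1 of 100 splits, the real one, had as many (real 2245, highest other 2124). A measure picked in this way does not exclude chance, and the count was 1431 without exercised MKO replicate 4. The split with 2124 kept the exercised libraries grouped by genotype, so it can carry a genotype effect too.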

How the results depend on the processing

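The comparison averaged over states, and leaving out 3 outlying libraries together, were chosen after the result was seen; the cause of each shift was not tested.

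Counts of genes moved as follows. Between genotypes at rest (1 gene) DESeq2 and limma-voom called 3 each, only the compared groups 2, and the fit without the 3 outlying libraries 3. In exercised muscle (5 genes) DESeq2 called 95 and no filter 2. For the difference between responses (0 genes; 534 at an unadjusted p under 0.05 in edgeR) total counts alone gave 1, DESeq2 3, limma-voom 4 and the fit without the 3 outlying libraries 3. For the average over states (2 genes) it was 4, 139, 10 and 6 in the same order. List calls with an estimated correlation and with fry were 0 and 0 at rest, 0 and 1 in exercised muscle, 3 and 7 for exercise in WT, 3 and 7 in MKO, 0 and 0 for the difference, and 0 and 0 for the average.

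With single libraries left out, the count ran from 1 to 3 genes at rest, 2 to 108 in exercised muscle, 808 to 943 for exercise in WT, 316 to 503 in MKO, 0 to 3 for the difference and 2 to 163 for the average, and the shared genes from 286 to 493. The values 108, 316, 3 (difference), 163 and 286 came without exercised MKO replicate 2. Lists called ran from 10 to 16 at rest, 8 to 11 in exercised muscle, 12 to 16 for exercise in WT, 15 to 19 in MKO, 7 to 11 for the difference and 8 to 14 for the average.

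The replicate numbers do not pair the libraries: 0 of 10 same-numbered pairs had a correlation of deviations over 0.1 (-0.153 to 0.0759), and 2 of 11 libraries correlated best with their own number. With the number as a replicate block (4 residual degrees of freedom against 8), the counts were 0 at rest, 2 in exercised muscle, 602 for exercise in WT, 361 in MKO and 293 shared. Among the calls lost were B230219D22Rik at rest (-2.29, adjusted p = 0.0545) and, in exercised muscle, Lgals8 (4.14, 0.0808), Egr1 (-1.84, 0.294), Sema3a (-1.75, 0.287) and Mnt (-0.75, 0.248).

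Among values of the 175 named-gene results, 2307 kept their sign and side of the threshold, 324 no longer passed, 7 newly passed and 26 changed sign, none of the 26 past the threshold. Atp2a2 at rest was -0.11 with limma-voom and -0.25 with the block, and in exercised muscle -0.36 with the block and -0.010 to 0.28 with single libraries left out. Its exercise response was -0.034 to 0.41 in WT with single libraries left out; in MKO it was 0.52 with limma-voom, 0.26 with the block and -0.50 to 0.34 with single libraries left out; the difference was 0.26 with limma-voom and -0.73 to 0.13 with single libraries left out. Ppargc1a in exercised muscle was 0.42 without the 3 outlying libraries and -0.68 to 0.38 with single ones left out, and its difference -0.12 to 0.94. Sln ran from -1.26 to 0.081 for exercise in WT and -0.45 to 2.17 in MKO, where it was -0.22 without the 3 outlying libraries. Atp2a1 was -0.037 for exercise in MKO with total counts only, and its difference was 0.0066 without the 3 outlying libraries and -0.20 to 0.039 with single ones left out.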

Other observations

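The comparison averaged over states, its tests and the 4 MHC class II genes were chosen after the result was seen.

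Between genotypes, 4 MHC class II genes had higher values in exercised MKO muscle and none passed; they were picked for their values, so a test of them as a group would show nothing. Cd74, the invariant chain of MHC class II, stood at 50.9 ± 5.20 CPM in sedentary WT, 63.1 ± 3.10 in sedentary MKO, 22.4 ± 5.55 in exercised WT and 49.6 ± 11.3 in exercised MKO muscle. In exercised muscle Cd74 (1.15 ± 0.19, adjusted p = 0.111), H2-Ab1 (1.21 ± 0.22, adjusted p = 0.141), H2-Aa (1.17 ± 0.23, adjusted p = 0.165) and H2-Eb1 (1.22 ± 0.26, adjusted p = 0.195) were the values in MKO against WT. Among the lists fixed in advance the macrophage score was 0.672 higher in MKO across both states (exact permutation test within states, p = 0.005, the smallest that 400 arrangements can give; adjusted over 32 lists p = 0.08) and the satellite cell and myogenic score 0.458 higher (p = 0.005, adjusted p = 0.08). By the same permutation test the fibro-adipogenic progenitor score was 0.305 and the ribosomal protein score 0.16 higher (p = 0.01, adjusted p = 0.08 for each).

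Averaged over states, Psat1 (1.13) was the 1 gene of the list of unfolded protein and integrated stress response genes to pass adjusted over the list alone (adjusted p = 0.0355; 0.155 over all genes, edgeR). The score of that list did not pass (exact permutation test within states, adjusted over 32 lists p = 0.133). In the same test even the macrophage score, at the smallest possible p of 0.005, had adjusted p = 0.08, so not passing says little. The matrix genes Col1a1 (0.92) and Col6a1 (0.45) were among 6 of 23 that passed adjusted over the list alone, and ribosomal protein genes were positive for 32 of 33 (median 0.17). Of 14486 genes 2 passed over all genes, Lgals8 and B230219D22Rik. At an unadjusted p under 0.05 there were 2245, with 2124 in the highest other split, which kept the exercised libraries grouped by genotype. There were 1431 without exercised MKO replicate 4 and 1484 without the 3 outlying libraries, so that the count depended on these libraries.

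Lgals8 fell in WT with exercise but did not pass in MKO (11.9 CPM in sedentary and 16.7 in exercised muscle), so that it separated exercised MKO from exercised WT by more than B230219D22Rik itself (3.93 against -2.64).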
